A study of Mus musculus with 14 samples.

How the data were processed

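The samples were 14 preparations of lymphatic endothelial cells from lymph nodes of C57BL/6 mice, taken from the subcapsular sinus, which receives the afferent lymph, or from the medullary (lymphatic) sinus on the efferent side. Per the labels, 10 samples held 50 cells each, cut by laser-capture microdissection (LCM) from frozen sections stained for CD31 and F4/80, 5 from each sinus. The other 4 samples, 2 from each sinus, held 1200 cells each, sorted by fluorescence (FACS) from enzymatically digested nodes with a lineage cocktail, anti-CD73, anti-podoplanin and a dead-cell dye. The RNA was amplified with the SuperAmp method, labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, 1 array per sample.

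Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, which removed spatial trends and background and gave each spot an intensity in arbitrary units with no scaling between arrays. The authors also deposited a table of log2 values whose distributions are nearly identical in every column, with a median of 5.43 on each array. How that table was made is not stated. Probe positions in the scanner files are on the mouse build mm9. The scanner files also place the arrays on 2 slides, each scanned once. Slide 1 held the 5 subcapsular LCM arrays and medullary LCM replicates 1 to 3. Slide 2 held medullary LCM replicates 4 and 5 and the 4 FACS arrays.

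The background-adjusted intensities were log2 transformed, and the 75th percentile of the array over all non-control probes was subtracted, so that each value is a log2 signal over that percentile. Spots marked as outliers by the scanner software were left out, and repeated spots of a probe were averaged. Of 55681 distinct non-control probes, 27235 took a current symbol through their RefSeq accession, 3581 and 565 through a current or an older symbol, and 24300 kept the name in the file. The plan had named genes by the file's own symbol column. The RefSeq route was added once the files could be read. A gene was represented by its probe with the highest mean over the 14 arrays, which left 34741 genes by name. Ccl21a, Ccl21b, Ccl21c, Hspa1b and Hbb-b1 were not matched by name and were not analysed, and Faim3 was counted as Fcmr.

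A gene entered the LCM comparison when its probe was well above background, as the scanner software calls it, on at least 3 of 5 arrays of a sinus. It entered the FACS comparison when this held on both arrays of a sinus, and the comparisons over all 14 arrays when either condition was met. Differences are medullary minus subcapsular, or FACS minus LCM. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with the data.table package, version 1.17.8, to read the files), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fits over 14 arrays had 4 group means and array weights by isolation. The interaction is the sinus difference in FACS minus that in LCM. Errors beside fitted differences are standard errors (SE). Where no array of a group was above background, the fold is a lower bound. It was computed against the lowest signal called above background on each array of that group, or against the measured signal where that was higher. In the fits over 14 arrays this was applied to each group with no array above background, and no value is given for fixed genes where it would not give a bound. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

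There were 30 gene lists, 17 of pathways or functions and 13 of markers of other cell types. They were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Alternatives were camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way and makes no comparison with other genes. The list of 3 genes followed up by the study (Siglec1, Msr1 and Emcn) was chosen by the study on these samples and is not independent evidence. The lists, the tests, the filter and the rule for named genes were set before the data were examined. For each sinus comparison the rule took the 10 largest called differences in each direction among genes whose groups did not overlap and whose higher group was above background throughout. Where fewer than 5 qualified, the list was filled to 5 by unadjusted p. The rule took 5 per direction for the interaction and for FACS minus LCM, the 4 members with the lowest p of each shifted list, and 13 fixed genes. Names that are only probe, clone, accession or LOC identifiers were counted and not named. This part of the rule had first been applied more strictly than written and was corrected after values had been seen.

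Alternatives were normexp background correction with an offset of 50, quantile normalization, a percentile over probes above background on all arrays, and the deposited log2 table. Others were a stricter filter and none, the mean of a gene's probes, trend and robust eBayes, other array weights, and 1 fit of all arrays. Slide and replicate number were tried as blocks, single slides were analysed alone, and each array was left out in turn. The row of the slide as a block was added after seeing the data. Groups were also compared with 100 splits of the same arrays into groups of the same sizes, drawn with a fixed seed and including the real split.

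Precision on these arrays is limited by their number and by the share of probes above background, which was 68.7% on the median array. The fits were tested on simulated data, drawn around each gene's mean with the normal spread fitted to its isolation, with known differences added. At differences of 2, 4 and 8 on the log2 scale, the LCM fit called 1.5%, 29.9% and 89.4% of the changed genes, with 7 false calls. The FACS fit called 0%, 0% and 34.8%, with 0 false calls. The interaction called 0%, 6% and 63.6%, with 16 false calls, and FACS minus LCM called 16.4%, 61.2% and 100%, with 15. The size of 8 was added after the FACS fit had called none of the smaller differences.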

Results

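Gene expression was measured in lymphatic endothelial cells of the mouse lymph node on 14 arrays, with 5 subcapsular and 5 medullary LCM samples and 2 subcapsular and 2 medullary FACS samples. The share of probes well above background was 50.78% to 69.04% on the subcapsular LCM arrays and 67.37% to 75.32% on the medullary LCM arrays. It was 66.3% and 77.86% on the subcapsular FACS arrays and 69.08% and 78.99% on the medullary FACS arrays. In LCM this share was 12.81 percentage points higher in medullary (71.45% ± 3.48, SD, n = 5) than in subcapsular samples (58.64% ± 6.67, SD, n = 5), with p = 0.0238 in an exact two-sided permutation test. On slide 1 alone the difference was 15.18 points (exact two-sided permutation p = 0.0179). The share also followed the row of the slide. It was 50.78% to 68.42% on the LCM arrays of row 1, subcapsular replicates 1 to 4 and medullary replicates 4 and 5. On those of row 2, subcapsular replicate 5 and medullary replicates 1 to 3, it was 69.04% to 75.32%. Medullary arrays were higher within each row, but in row 1 they lay on the other slide. Sinus and row are thus only partly told apart in LCM. The 2 FACS groups differed by 1.96 points, where an exact two-sided permutation test gave p = 0.667 and could not go below 0.33. Correlations across genes between arrays of a group were 0.683 to 0.764 for subcapsular LCM, 0.745 to 0.814 for medullary LCM, 0.857 for subcapsular FACS and 0.733 for medullary FACS. The labels do not tie samples to animals. Some LCM samples may share an animal, and where samples of the same sinus do, the p-values below are too small. Sharing across the sinuses would leave a pairing that the main fits ignore.

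The LCM arrays ask which genes differ between the endothelium of the subcapsular and of the medullary sinus in tissue sections. Of 27324 genes tested, 46 were higher and 2 lower in the medullary sinus, a balance that held for the main scaling and not for others given below, and 3193 had an unadjusted p under 0.05 where chance gives 1366. Itih3, a heavy chain of the inter-alpha-trypsin inhibitor family, was at least 69.9-fold higher (7.22 ± 0.65 on the log2 scale, SE, n = 5 per sinus, limma adjusted p = 0.00385). It was above background on 5 of 5 medullary and 0 of 5 subcapsular arrays. Fut7, the fucosyltransferase that builds selectin ligands in high endothelial venules, was 108-fold higher (6.76 ± 0.64, limma adjusted p = 0.00385). Pcdh12, a protocadherin of endothelial cells, and Sv2a, a synaptic vesicle protein, were at least 56.9-fold and 31.9-fold higher. Angpt2, a ligand of the endothelial receptor Tie2, was at least 52.1-fold higher (limma adjusted p = 0.0229), and the growth factor gene Bmp3 at least 22.7-fold. With normexp background correction Itih3 was higher by only 3.38, Pcdh12 by 3.02, Sv2a by 2.37, Angpt2 by 3.1 and Bmp3 by 2.09, with Sv2a, Angpt2 and Bmp3 no longer called, so these lower bounds hold for the main processing only. Ctla2a was higher by 6.25 and Prdx6b by 5.98 on the log2 scale, and by 3.77 and 2.49 with normexp. Dsg4 and Nrn1 were higher by 6.28 and 6.14, but for each of them 1 of 2 probes pointed the other way. The called genes that were lower in the medullary sinus were Ccl12, a chemokine ligand of CCR2, which fell by 5.41 on the log2 scale (SE 0.52, limma adjusted p = 0.00385), and Snx13, a sorting nexin, which fell by 5.26 (SE 0.86, limma adjusted p = 0.0471). For all of these genes, each medullary array lay on the same side of every subcapsular array, as the rule for named genes required. Without medullary replicate 2 the calls of Angpt2 (adjusted p = 0.0513), Prdx6b (0.0512), Ctla2a (0.0636) and Dsg4 (0.0598) ended, as did that of Ctla2a without subcapsular replicate 2 (0.0512) and that of Dsg4 without subcapsular replicate 4 (0.0521). The calls of Snx13 and Nrn1 ended without any 1 of 9 and 8 of the 10 arrays, with limma adjusted p of at most 0.0981.

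Some of the probes behind these values lie, on mm9, on chromosome 14 from 31721835 to 31721894 for Itih3 (NM_008407), on chromosome 2 from 25281802 to 25281861 for Fut7 (NM_013524), on chromosome 18 from 38426868 to 38426927 for Pcdh12 (NM_017378), and on chromosome 11 from 81916764 to 81916823 for Ccl12 (NM_011331).

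Markers of blood endothelium and high endothelial venules rose in the medullary LCM samples as a list (median difference 1.55, 15 of 19 members positive, camera adjusted p = 2.24e-05). The adjusted p with an estimated correlation was 0.0622. Of its members, Fut7, Ackr1 and Chst4 were called over all genes tested, and 7 were called adjusted over the list alone. Ackr1, the atypical chemokine receptor of venules, was higher by 5.44 ± 0.65 (SE, limma adjusted p = 0.0163). Chst4, the sulfotransferase that completes L-selectin ligands, was higher by 4.47 ± 0.73 (SE, limma adjusted p = 0.0471), and its call ended without any 1 of 9 of the 10 arrays (adjusted p from 0.0618 to 0.0983). Vwf differed by 5.84 and did not pass (limma adjusted p = 0.0972). Of the 20 genes in this list, 12 also stand in another list.

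Macrophage markers fell as a list (median −1.75, 23 of 24 members negative, camera adjusted p = 2.43e-10, adjusted p = 0.138 with an estimated correlation). No member was called over all genes, and 9 were called adjusted over the list alone. Timd4, a phosphatidylserine receptor, differed by −3.12, the lysozyme genes Lyz1 and Lyz2 by −2.8 and −2.82, and Siglec1 by −4.54. Scavenger and lectin receptors also fell (median −1.43, 22 of 28 members negative, camera adjusted p = 0.000418, adjusted p = 0.0622 with an estimated correlation). No member was called over all genes and 4 were called adjusted over the list alone, among them the fatty acid receptor gene Cd36 (−4.83, limma adjusted p = 0.053) and Marco (−2.14, limma adjusted p = 0.217). B cell markers fell (median −1.35, 12 of 15 negative, camera adjusted p = 5.01e-07, adjusted p = 0.0622 with an estimated correlation), with 6 called adjusted over the list alone, including Ms4a1 at −1.94 and Cd79a at −1.48. Antigen presentation genes fell (median −0.95, 20 of 28 negative, camera adjusted p = 6.03e-05, adjusted p = 0.21 with an estimated correlation), with none called adjusted over the list alone. H2-DMa had the lowest p of that list, at −2.53. The call of that list ended after quantile normalization (camera adjusted p = 0.419) and with the deposited log2 values (0.425). Its median lay at −1.03 relative to that of all genes, close to the −0.9 of 15 housekeeping genes chosen after seeing the data, of which 14 lay below the median of all genes. The macrophage, scavenger and B cell lists lay at −1.83, −1.51 and −1.43.

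Siglec1, Msr1 and Emcn, which the study followed up, differed by −4.54 ± 0.87, −4.57 ± 1.1 and 5.08 ± 1.19 (SE). In each case the groups did not overlap, and the limma adjusted p over all genes was 0.0843, 0.175 and 0.161. As a list chosen on these samples they are not independent evidence. The list did not pass with camera (camera adjusted p = 0.242) and passed with fry (fry adjusted p = 0.0368). Because Emcn moved against Siglec1 and Msr1, a test of a shift 1 way cannot decide whether the 3 genes differ. Of the lymphatic genes, Lyve1 differed by −0.61, Prox1 by −1.21, Ackr4 by −5.43, Madcam1 by 1.07 and Mrc1 by −2.49, with limma adjusted p from 0.326 to 0.887. Pecam1 and Adgre1, whose proteins were stained for dissection, differed by 0.64 and −0.81, and Nt5e and Pdpn by 4.2 and 2.31, with none called. Ralgps2 and Cxcl13, next in order of p among lower genes, differed by −3.07 and −2.96 and did not pass (limma adjusted p = 0.0535 and 0.0606).

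The other 25 lists did not pass in LCM, with camera adjusted p from 0.109 to 0.779. Of these, the median was positive for cell division (1.06), T cell (1.01), NK cell (0.91), erythroid cell (1.54), neutrophil (0.86), basement membrane and extracellular matrix (0.31), endothelial junctions and valves (0.39), immediate early and dissociation response (0.64), lymphatic endothelial identity (0.59), adipocyte (0.47), platelet and megakaryocyte (0.37), chemokines and chemokine receptors (0.95), vascular growth factor and angiopoietin signalling (0.08), and subcapsular sinus endothelial markers (0.15). It was negative for sphingosine 1-phosphate and lysophospholipid handling (−0.64), lipid uptake and fatty acid handling (−0.13), interferon-stimulated genes (−0.18), fibroblastic reticular and mesenchymal cell (−0.41), dendritic cell (−0.25), medullary sinus endothelial markers (−0.74), leukocyte adhesion and traffic (−0.02) and plasma cell (−0.02). For leukocyte adhesion and plasma cell genes the mean (0.62 and 0.33) and the test pointed up. For Notch, BMP and TGF-beta signalling the median was 0.18 and the test pointed down, and for smooth muscle cells and pericytes the median was 0 and the test pointed up. Subcapsular sinus markers had a mean of −0.05 beside their positive median.

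The count of 48 called genes and its balance moved with the scaling. It was 22 with normexp (12 higher, 10 lower), 15 after quantile normalization (10 and 5), 17 with the deposited values (12 and 5) and 229 with the percentile over probes above background on all arrays (220 and 9), which shifts every gene alike. The median probe lay 0.95 higher relative to the 75th percentile on the medullary than on the subcapsular LCM arrays (exact two-sided permutation p = 0.0159), so the excess of higher genes is tied to the scaling. The count also moved with single arrays, being 23 without medullary replicate 2, 97 and 104 without medullary replicates 4 and 5, and 100 without subcapsular replicate 5. With slide as a fixed block it was 127, on slide 1 alone 248, with the row of the slide as a block 14, and with the replicate number as a block 0. On slide 1 sinus and row nearly coincide, as only subcapsular replicate 5 lay in the row of the medullary arrays.

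**Figure D1:**
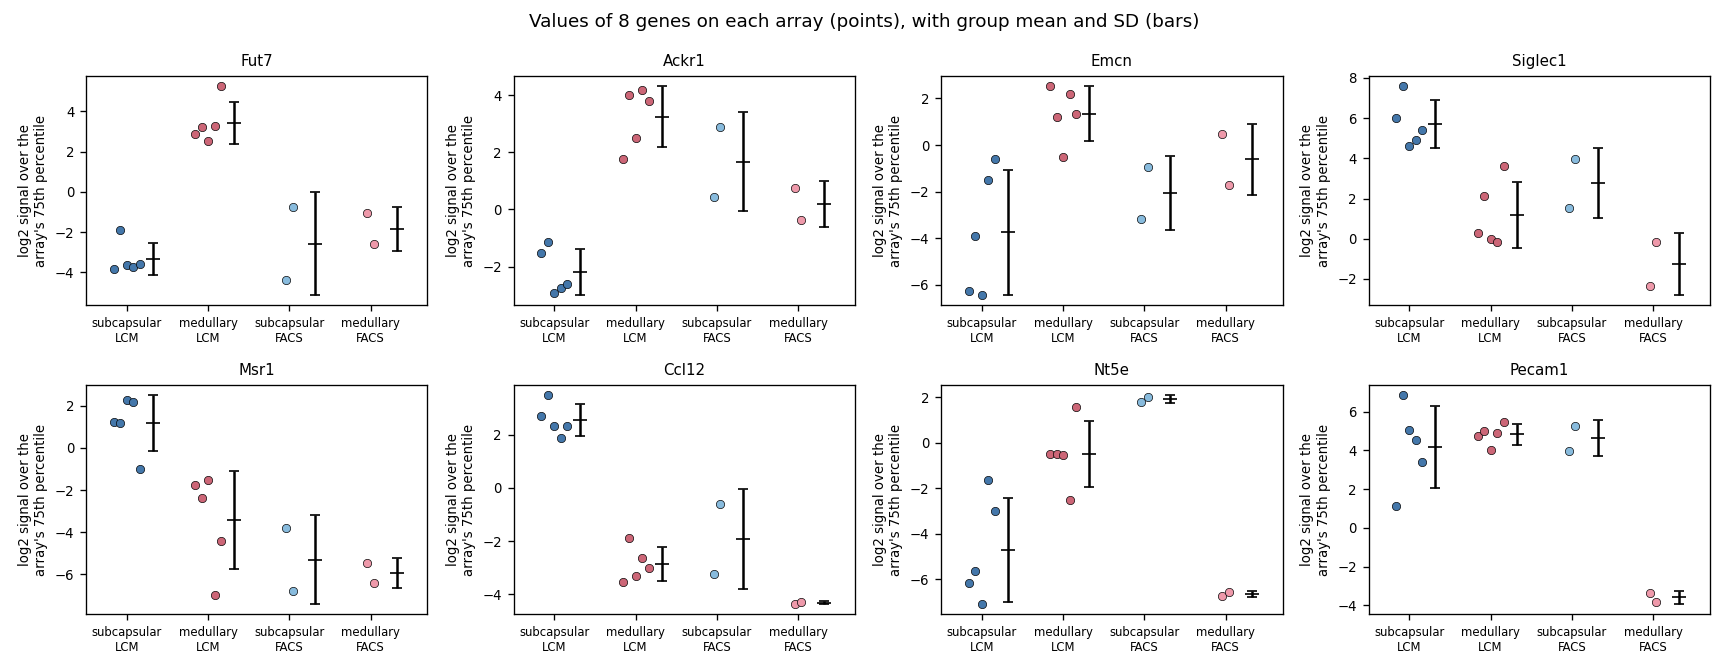
Signal of 8 genes on each array, as log2 over the array's 75th percentile, for the 4 groups on the horizontal axis; points are arrays and bars give the group mean and SD. The medullary LCM arrays lie above every subcapsular LCM array for Fut7, Ackr1 and Emcn and below every one for Siglec1, Msr1 and Ccl12, and Nt5e is above background on 2 of 2 subcapsular and 0 of 2 medullary FACS arrays.

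The FACS arrays ask the same question in sorted cells, with 2 arrays per sinus. No gene of 27628 was called by limma, 8810 had an unadjusted p under 0.05 where chance gives 1381, and the smallest adjusted p was 0.0648. That value was shared by the genes closest to the threshold. Among them Tdrd9, Gm4211, Vill, Obp2a and Olfr1272 were at least 175-fold, 83.5-fold, 64-fold, 45-fold and 33.1-fold higher in the medullary samples, each above background on 2 of 2 medullary and 0 of 2 subcapsular arrays. In the other direction, Crisp1, Npepps, Hip1r, Tfrc and Cdk17 were at least 589-fold, 307-fold, 232-fold, 195-fold and 156-fold lower. Tfrc encodes the transferrin receptor and Hip1r an endocytic adaptor. None of these 10 genes passed the threshold. With normexp Tdrd9 and Crisp1 were at 4.58 and −6.75, so these folds also hold for the main processing only. Nt5e, which encodes the sort antigen CD73, was at least 92.9-fold lower in the medullary samples and Pdpn differed by 4.33. Both encode proteins stained for sorting and are not findings, and the labels do not say which sign of CD73 defined which sorted population. Pecam1 differed by −8.22 ± 0.74 (SE), and Ackr4, a scavenging receptor for CCL19 and CCL21, was at least 32.5-fold lower (limma adjusted p = 0.0648 for both). Siglec1 differed by −4.02, Mrc1 by −2.62, Adgre1 by −2.25, Prox1 by 1.94, Emcn by 1.44, Madcam1 by 1.21 and Marco by 0.03, with none called, and Lyve1 and Msr1 did not enter this comparison.

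Immediate early and dissociation genes fell in the medullary FACS samples as a list (median −2.24, 33 of 34 members negative, camera adjusted p = 1.42e-07), with 5 called adjusted over the list alone. Zfp36 differed by −5.06, Myc by −7.72, Egr2 by −3.68 and Dusp1 by −3.7. Antigen presentation genes fell (median −1.84, or −1.59 with 2 members at their bound, 24 of 29 negative, camera adjusted p = 7.61e-05), with Tap1 at least 169-fold lower, Psmb9 at −5.2 and B2m at −4.07. B cell markers fell (median −2.06, 14 of 15 negative, camera adjusted p = 0.000186), as did cell division genes (median −1.85, 20 of 26 negative, camera adjusted p = 0.000588), with Mcm3 at least 32.6-fold lower and Bub1b at −5.33. Interferon-stimulated genes (median −0.97, 20 of 28 negative), chemokines and their receptors (median −1.59, 24 of 32 negative) and T cell markers (median −1.73, 17 of 20 negative) fell with a camera adjusted p of 0.0049 each. Gbp3 was at least 59.1-fold and Ccl4 at least 8.09-fold lower, and Cxcl10 differed by −5.09 and Tcf7 by −4.6. Adjusted over the list alone, 4 antigen presentation genes, 1 B cell gene, 4 cell division genes, 7 interferon-stimulated genes, 5 chemokine genes and 0 T cell genes were called, and 0 over all genes. With an estimated correlation none of the 7 lists passed, and the smallest adjusted p was 0.458. Housekeeping genes fell about as far, since relative to the median of all genes 15 of 15 chosen after seeing the data lay below it, at −2.22, and the 7 lists lay at −2.97 to −1.7. The falls of these lists are therefore not shown to be specific to their pathways or cell types.

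The other 22 lists tested in FACS did not pass (camera adjusted p from 0.081 to 0.93). Among them were macrophage (median −0.93), subcapsular sinus markers (−1.28), lymphatic endothelial identity (−1.73), blood endothelium and high endothelial venules (−0.24) and medullary sinus markers (0.15). The median and the test differed in sign for NK cell, medullary sinus, endothelial junction, Notch and smooth muscle genes. The median of all genes in this comparison was 0.73. For FACS the sinus and the row of the slide cannot be told apart, because both subcapsular arrays lay in row 1 and both medullary arrays in row 2. The count of 0 became 1800 with trend and robust eBayes and 893 with all 14 arrays in 1 fit.

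**Figure D2:**
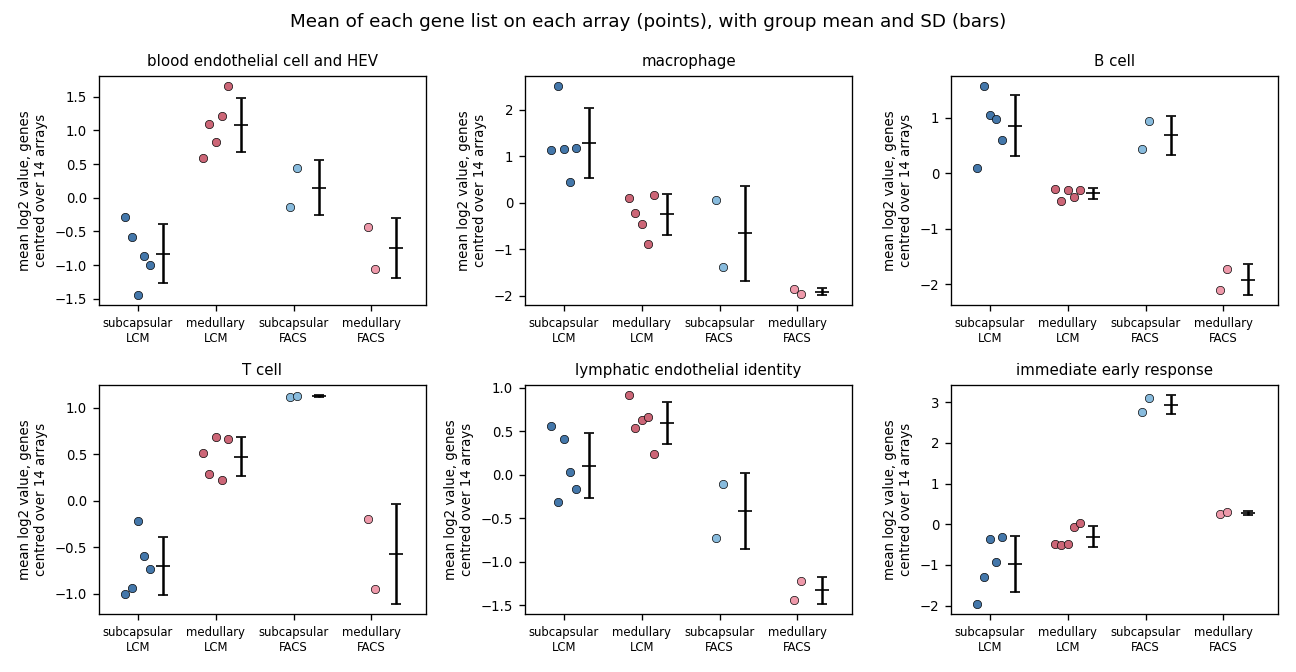
Mean log2 value of 6 gene lists on each array, each gene centred over the 14 arrays, for the 4 groups on the horizontal axis; points are arrays and bars give the group mean and SD. Blood endothelial and high endothelial venule (HEV) genes rose from the subcapsular to the medullary LCM samples with a median of 1.55, macrophage genes fell with a median of −1.75, and immediate early genes were highest in the subcapsular FACS samples. With an estimated correlation neither LCM shift passed (camera adjusted p = 0.0622 and 0.138).

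Whether the sinus difference itself differed between sorted and dissected cells was tested as an interaction over 29601 genes. It was called for 382, of which 163 were more positive and 219 more negative in FACS. The largest positive values were those of HOTAIR (5.63 ± 0.98, SE), a long noncoding RNA, Gm12695 (5.4), Cpxm2 (5.35), the olfactory receptor gene Olfr56 (5.34) and the rhodopsin kinase gene Grk1 (5.32), with limma adjusted p from 0.00849 to 0.032. The largest negative values were those of Cmc1 (−14.71 ± 1.64, SE), Nt5e, Mtres1 (−11.17), Net1 (−11.15) and Poglut1 (−10.89), with limma adjusted p from 0.0015 to 0.0483. Pecam1 was also called (−8.86, limma adjusted p = 0.0122). Nt5e lay 4.2 higher in the medullary LCM samples and was below background on both medullary FACS arrays. Its interaction was −10.74 or further from 0, with the signal there set to the lowest called above background, so its place among these genes is not fixed. Neither Siglec1 (0.52) nor Emcn (−3.65) was called. Nor were Prox1 (3.15), Madcam1 (0.14), Marco (2.16), Mrc1 (−0.13), Adgre1 (−1.44) and Pdpn (2.02), nor Msr1, Ackr4 and Lyve1, for which no value is given because they were below background on both medullary FACS arrays. Without subcapsular FACS replicate 7 the call ended for 9 of the 11 genes called above, all but Cmc1 and Mtres1, with adjusted p from 0.0723 to 0.259. Without subcapsular FACS replicate 6 it ended for HOTAIR, Gm12695, Cpxm2, Olfr56, Grk1 and Poglut1 (adjusted p from 0.0507 to 0.158), and Olfr56, Grk1 and Poglut1 also lost it without some single LCM arrays, and Poglut1 without medullary FACS replicate 7 (0.0671). The count was 96 and 11 without subcapsular FACS replicates 6 and 7 and 1268 and 1113 without medullary FACS replicates 6 and 7, where the remaining array is assumed to vary like the other groups, and 36 more positive with 71 more negative without array weights. Its balance also changed, to 362 more positive and 303 more negative with normexp (665 in all), 108 and 360 with the percentile over probes above background on all arrays, 717 and 396 without medullary FACS replicate 7, and 2 and 9 without subcapsular FACS replicate 7. It was 1140 after quantile normalization, 1114 with the deposited log2 table, 186 with slide and 216 with its row as a block, and 0 with the replicate number as a block.

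FACS minus LCM was taken as the average over both sinuses. The isolations differ in cell number, node sites and handling at once, in slide for 8 of the 10 LCM arrays, and in sex-linked transcripts, as Ddx3y was above background on 10 of 10 LCM and 0 of 4 FACS arrays and Xist was 4.5 higher in FACS. Of 29601 genes, 539 were higher and 605 lower in FACS, a balance that turned under other settings given below. By fitted value the largest positive differences were those of the androgen-binding protein genes Scgb1b27 (10.57 ± 0.77, SE, limma adjusted p = 2.49e-06) and Scgb2b27 (10.3 ± 0.57, SE, limma adjusted p = 1.32e-07), the cystatin gene Cst10 (9.29), the chitinase gene Chia1 (8.88) and the salivary gene Smr3a (8.73). Each was above background on 4 of 4 FACS arrays and higher on all of them than on every LCM array, as the rule for named genes required. All but Smr3a were below background on every subcapsular LCM array, and the lower bounds of their differences were 10.21, 9.95, 8.88 and 8.3. By fitted value the largest negative ones were those of Gm20867 (−9.98), Gm20865 (−8.94 at its bound), Gm20806 (−8.74 at its bound), Gm20747 (at least 366-fold lower) and Gm20822 (at least 247-fold lower). Every LCM array lay above every FACS array, as the rule for named genes required. Ddx3y split the arrays in the same way. For these 5 genes isolation therefore cannot be told apart from the difference in sex-linked transcripts. With normexp Gm20747 and Gm20822 were at −5.87 and −5.15, so their folds hold for the main processing only.

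Immediate early and dissociation genes rose in FACS (median 1.99, 29 of 34 positive, camera adjusted p = 3.13e-08, adjusted p = 0.00124 with an estimated correlation), with 7 members called over all genes and 11 adjusted over the list alone. The transcription factor genes Fosb, Fos and Jun and the receptor gene Nr4a1 were higher by 6.77, 6.92, 3.64 and 5.28. The rise came mainly from the subcapsular samples, where the list's centred mean was 2.77 and 3.1 on the FACS arrays against 0.24 and 0.31 on the medullary ones. On the medullary arrays of slide 2 alone the list's median lay only 0.01 above that of all genes in FACS. Macrophage markers fell (median −1.74, 23 of 25 negative, camera adjusted p = 7.17e-10, adjusted p = 0.0392 with an estimated correlation), with Timd4 at −5.27 and Hmox1 at −3.27, and 7 called over all genes. Fibroblastic reticular and mesenchymal genes fell (median −1.14, camera adjusted p = 8.8e-07, adjusted p = 0.0187 with an estimated correlation), with Col3a1 at −4.64, Pdgfra at −4.71 at its bound and Cxcl13 at −6.51. Lymphatic endothelial identity genes fell (median −1.16, camera adjusted p = 0.000446, adjusted p = 0.0187 with an estimated correlation), with Pecam1 at −3.99 and Cdh5 at −2.33 at its bound called. This fall was larger in the medullary samples, where the list's centred mean was −1.44 and −1.22 in FACS against 0.24 to 0.91 in LCM. In the subcapsular samples it was −0.73 and −0.11 in FACS against −0.31 to 0.56 in LCM. The value of Pecam1 averages over unlike sinuses, as its means were 4.62 in FACS and 4.18 in LCM for the subcapsular and −3.6 and 4.82 for the medullary sinus. Scavenger and lectin receptors fell (median −0.91, camera adjusted p = 0.000236, adjusted p = 0.021 with an estimated correlation), with Msr1 at −3.84 at its bound, Cd209b at −4.54 and Clec2d at −1.62 called.

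A further 7 lists fell with the preset correlation only. They were leukocyte adhesion and traffic (camera adjusted p = 3.47e-05), antigen presentation (4.47e-05), medullary sinus markers (0.000161), B cell (0.000236), the genes followed up by the study (0.0117), subcapsular sinus markers (0.0222) and lipid uptake (0.0222). With an estimated correlation their adjusted p was 0.0941, 0.0862, 0.0625, 0.0673, 0.0625, 0.0625 and 0.192. With slide as a fixed block the calls of the followed-up genes (camera adjusted p = 0.105), lipid uptake (0.261) and subcapsular sinus markers (0.383) ended, the last with a median relative to all genes of −0.08 in place of −0.56. On the medullary arrays of slide 2 alone those of lipid uptake (0.293), both sets of sinus markers (0.0814 each) and scavenger receptors (0.162) ended. The other 18 lists did not pass (camera adjusted p from 0.0775 to 0.949). The median and the test differed in sign for matrix, chemokine, interferon-stimulated, neutrophil and endothelial junction genes. Of the fixed genes not called, Siglec1 differed by −2.7, Lyve1 by −1.83 at its bound, Mrc1 by −2.06, Adgre1 by −1.39, Marco by −1.1, Pdpn by 1.02, Prox1 by 0.68, Madcam1 by −0.15 and Emcn by −0.14. Nt5e and Ackr4 were not called either, and no value is given because they were below background on both medullary FACS arrays. The calls of Smr3a, Fos, Pdgfra and Cdh5 ended without either subcapsular FACS array (adjusted p from 0.0539 to 0.109), that of Pecam1 without replicate 6 (0.0573) and that of Msr1 without replicate 7 (0.106), and those of Cd209b and Clec2d without any 1 of 11 and 13 of the 14 arrays. The count of 1144 was 163 with slide as a fixed block, 2312 with slide as a random block, 747 without array weights, and 610 and 631 without subcapsular FACS replicates 6 and 7. On the medullary arrays of slide 2 alone, 2 against 2, it was 0. The balance became 361 higher and 630 lower with normexp, 799 and 559 with the percentile over probes above background on all arrays, and 1224 and 1088 with slide as a random block.

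**Figure D3:**
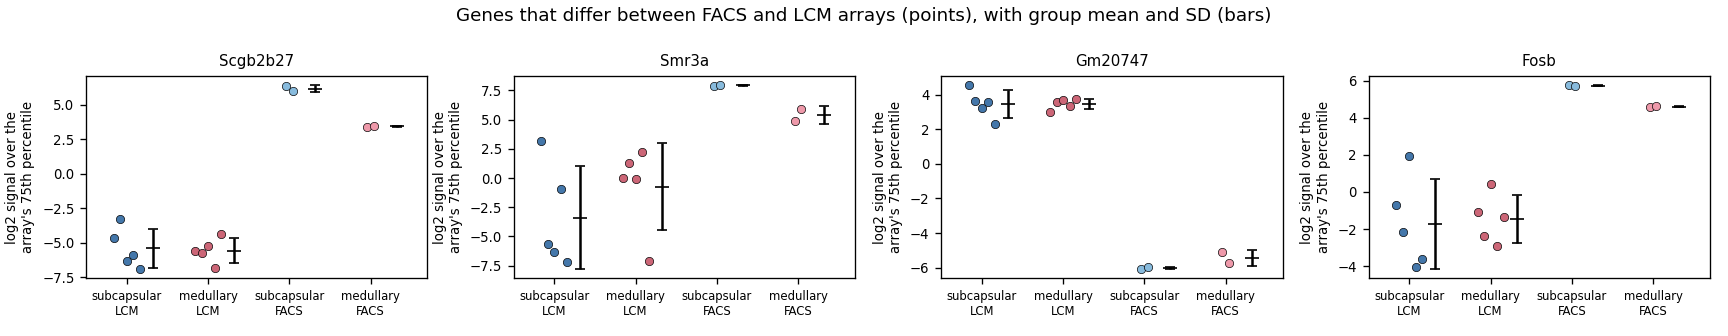
Signal of 4 genes on each array, as log2 over the array's 75th percentile, for the 4 groups on the horizontal axis; points are arrays and bars give the group mean and SD. Scgb2b27, Smr3a and Fosb were higher in FACS than in LCM samples by 10.3 (9.95 at its bound), 8.73 and 6.77, and Gm20747 was at least 366-fold lower.

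The sinus differences of the 2 isolations were compared across the 25295 genes in both fits, which share no array. Genes are not independent replicates. Pearson's r across genes was 0.149 and Spearman's rho 0.187. Of the 37 genes called in LCM and tested in FACS, 22 had the same sign in FACS, among them Ccl12 and Snx13. Angpt2 and Ackr1 (−1.48) had the opposite sign there, and Fut7 was at 0.74. Of all genes in both fits, 55.6% had the same sign. Among 100 splits of the LCM arrays, the real one included, 21 gave an r with FACS as far from 0, of either sign, so the relation was not beyond what other splits gave. With quantile normalization r was 0.018, and with the deposited log2 values 0.011. With each array left out in turn it ranged from 0.096, without subcapsular LCM replicate 3, to 0.207, without subcapsular LCM replicate 1.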

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

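The housekeeping and slide row tests in this part were chosen only after the result was seen.

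In 9 of the 96 sets of 5 LCM arrays examined, 1 array stood apart from the other 4, and chance marks about 1 in 20 such sets. The figure given for each is its gap to the nearest array over the range of the group. In the subcapsular group this held for Fut7 in replicate 2 (0.872), at −1.89 against −3.81 to −3.57 in the others. Nrn1 in replicate 4 (0.885) was at −0.12 against −5.26 to −4.67, and Pdpn in the same sample (0.722) at −0.55 against −7.4 to −5.5. Ralgps2 (0.783) and Ctss (0.72) in replicate 2 were at 3.94 and 4.83. In the medullary group Fut7 in replicate 5 (0.732) was at 5.24 against 2.54 to 3.27, and Nrn1 in replicate 1 (0.753) at 0.64. Ralgps2 in replicate 3 (0.736) was at −1.21, and Chst4 in replicate 1 (0.854) at 0.4 against 3.35 to 3.85.

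The sinus difference was not the same in FACS and LCM, by the interaction test, for HOTAIR (5.63), Gm12695 (5.4), Cpxm2 (5.35), Olfr56 (5.34), Grk1 (5.32), Cmc1 (−14.71), Nt5e (−12.76), Mtres1 (−11.17), Net1 (−11.15), Poglut1 (−10.89) and Pecam1 (−8.86). Nt5e was below background on both medullary FACS arrays, with a bound of −10.74. It encodes the sort antigen CD73, and the labels do not say which sign of CD73 defined which sorted population.

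Many widely expressed genes, Tfrc and Npepps among them, were below background on both medullary FACS arrays. Of the 15280 genes above background on the other 12 arrays, 191 and 365 were missing on medullary FACS replicates 6 and 7. Of genes seen on every other array, 0.69% and 1.84% were missing on these replicates against 0.49% to 4.89% on the subcapsular LCM arrays. Those shares leave out genes missing on both medullary FACS arrays, so they do not measure this pattern. Loss of transcripts on each array by itself is argued against, because of 15280 genes above background on the other 12 arrays 88 were missing on both and 6.2 were expected, a ratio of 14.25. Another cell type in these samples stays open, because the 15 housekeeping genes, at −2.22 relative to all genes, restate the pattern. Some endothelial genes were low too, with Pecam1 at −8.22 and Lyve1 above background on 0 of 2 arrays, against 1 of 2 subcapsular ones. The lymphatic identity list lay at −2.47 relative to all genes, with 12 of 18 members negative, but did not pass (camera adjusted p = 0.117). Other endothelial genes were mixed. Endothelial junction and valve genes lay at −0.1 as a list, with 16 of 23 positive, and Prox1 and Emcn were higher without being called. Adjusted over that list alone, 2 members were called lower and 0 higher. Cdh5 was at −6.51 and −5.16 on the medullary against −3.12 and −2.22 on the subcapsular FACS arrays. The row of the slide cannot be told apart from the sinus, since 0 of the 2 FACS groups span both rows. A loss shared by both medullary sorts before amplification and a difference between the sinuses stay open and were not tested.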

How the results depend on the processing

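The row of the slide as a block was chosen after seeing the data, and every other alternative before. Of the genes called in LCM, Itih3, Fut7, Pcdh12, Ackr1 and Ccl12 kept their direction and call in 24 of 25 settings, losing the call with the replicate number as a block (adjusted p from 0.162 to 0.171). With normexp Itih3 and Pcdh12 fell to 3.38 and 3.02. Chst4 and Snx13 kept it in 8 and Nrn1 in 6 of 25. The macrophage, B cell, blood endothelial and scavenger lists in LCM kept theirs in 26 of 27 settings, and antigen presentation in 24. The cause of a change was not tested except where fewer arrays or genes entered. The median of all genes moved from 0.08 in LCM, 0.73 in FACS, 0.52 in the interaction and 0.17 in FACS minus LCM to −0.16, 0.61, 0.7 and −0.02 with normexp, −0.02, 0.39, 0.38 and 0.05 with quantile normalization, 0.81, 0.84, −0.1 and 0.4 with the percentile over probes detected on all arrays, and −0.01, 0.43, 0.4 and 0.04 with the deposited log2 table. List values here are medians relative to all genes, and a list is said to reverse where the direction of its test turned, which can happen at an unchanged median. Nt5e, Ackr4, Lyve1 and Msr1 were below background on both medullary FACS arrays, so signs of theirs that rest on those arrays are not measured. Fewer probes were above background on the subcapsular LCM arrays, so several folds against them are lower bounds.

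With the estimated correlation 0 lists were called in LCM, 0 in FACS and 5 in FACS minus LCM. Under fry the direction turned for Notch genes in LCM (0.1) and FACS (0.06), smooth muscle genes in FACS (−0.02), and endothelial junction (0.51) and neutrophil genes (0.09) in FACS minus LCM. With normexp the calls were 22 in LCM and 665 in the interaction, and Marco (−0.08), Notch genes (0) and junction genes (−0.02) in FACS, Ackr4 (0.92) and Mrc1 (0.72) in the interaction, and neutrophil genes (0.01) in FACS minus LCM reversed. With quantile normalization the calls were 15 in LCM and 1140 in the interaction and the agreement was 0.018, and adipocyte genes in LCM (0.06), erythroid genes in FACS (−0.05) and Siglec1 in the interaction (−0.59) reversed. With the deposited log2 table they were 17, 1114 and 0.011, and the same items reversed at 0.02, −0.03 and −0.45. With the percentile over probes detected on all arrays LCM had 229 calls. This scaling shifts all genes of a comparison alike, so genes near 0 turn by that shift alone, and Lyve1 (0.12) and subcapsular sinus markers (0.07) in LCM, Madcam1 (−0.48), Siglec1 (−0.11) and Lyve1 (−0.33) in the interaction, and Emcn (0.09), Madcam1 (0.09) and Ackr4 (0.15) in FACS minus LCM reversed.

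The strict filter gave 104 calls in LCM, with fewer genes tested, and Notch genes reversed (0.06). With the mean of a gene's probes, subcapsular sinus markers in LCM (−0.1), Notch genes in FACS (0.1), and Ackr4 (0.79), Madcam1 (0.19), Pdpn (−0.15) and chemokine genes (0.11) in FACS minus LCM reversed. Trend and robust eBayes gave 1800 calls in FACS, and 1 fit of all arrays 893, with smooth muscle genes reversed (−0.02). With no filter the interaction called 254. Without array weights it called 36 more positive and 71 more negative genes (1.1e+02 in all), and FACS minus LCM 747.

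With slide as a fixed block the calls were 127 in LCM, 186 in the interaction and 163 in FACS minus LCM. Notch (0.13) and plasma cell genes (−0.03) in LCM, Madcam1 in the interaction (−0.29), and Bank1 (0.21), Tubb1 (−0.11), Madcam1 (0.72), Ackr4 (0.2), T cell (−0.02), adipocyte (−0.32) and interferon-stimulated genes (0.69) in FACS minus LCM reversed, and the calls there of the followed-up genes, lipid uptake and subcapsular sinus markers (−0.08) ended. With slide as a random block they were 88 in LCM and 2312 in FACS minus LCM. Slide 1 alone gave 248 in LCM, with Notch genes reversed (0.09). The medullary arrays of slide 2 alone gave 0 for FACS minus LCM, with 2 arrays a side, and Nt5e (−6.15), Madcam1 (0.57), Rgcc (−0.97), T cell (−1.11), cell division (−0.52), dendritic cell (−0.08), immediate early (0.01) and plasma cell genes (−0.71) reversed. With the replicate number as a block there were 0 calls in LCM and 0 in the interaction, and junction genes in FACS reversed (−0.1). Deviations of same-numbered LCM arrays correlated between −0.02 and 0.005, so no pairing by number was seen. Whether this check could have seen a pairing was not tested, and the labels do not tie samples to animals, so a pairing stays possible. With the row of the slide as a block LCM had 14 calls and the interaction 216, and Lyve1 (0.06), Notch genes (0.25) and subcapsular sinus markers (0.02) in LCM and Madcam1 in the interaction (−0.32) reversed.

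With each array left out in turn, the calls ranged from 23 to 104 in LCM, from 11 to 1268 in the interaction and from 610 to 1662 in FACS minus LCM, with fewer samples each time. Where 1 FACS array of a sinus was left, it is assumed to vary like the other groups. In LCM, Pecam1 ranged from −0.13 to 1.3, Lyve1 from −1.34 to 0.04, and immediate early genes from 0.24 to 0.78, subcapsular sinus markers from 0.01 to 0.29 and Notch genes from −0.2 to 0.33. In FACS, Marco ranged from −0.34 to 0.39, and smooth muscle genes from −1.54 to 0.17, Notch genes from −0.93 to 0.57, erythroid genes from −1.97 to 1.37, junction genes from −0.08 to 0.3 and medullary sinus markers from −0.44 to 0.15. In the interaction, Madcam1 ranged from −0.14 to 0.39, Lyve1 from −0.84 to 1.43, Mrc1 from −0.8 to 0.41 and Siglec1 from −0.71 to 1.75. In FACS minus LCM, Nt5e ranged from −0.05 to 0.63, Ackr4 from −0.81 to 0.41, Emcn from −0.7 to 0.42 and Prox1 from −0.13 to 1.49. Junction genes ranged there from 0.17 to 0.67, neutrophil genes from −0.21 to 0.3, erythroid genes from −1.1 to −0.18 and dendritic cell genes from −0.08 to 0.91.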

Other observations

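The scaling counts and the splits of the arrays in this part were chosen only after the result was seen. The second lists of genes were written after the patterns had been noticed and before their own values were read.

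Some genes of the Y chromosome were lower in FACS. Ddx3y was above background on 10 of 10 LCM and 0 of 4 FACS arrays and differed by −6.84 ± 0.54 (SE, limma adjusted p = 5.06e-06). Kdm5d differed by −5.56 and Eif2s3y by −3.53, although Eif2s3y was above background on 3 of 4 FACS arrays. Uty did not separate the isolations, being above background on 3 of 10 LCM and 1 of 4 FACS arrays with means of −5.59 and −5.45. Xist, the noncoding RNA of the inactive X chromosome, was above background on 8 of 10 LCM and 4 of 4 FACS arrays and differed by 4.5 ± 0.71 (SE, limma adjusted p = 0.0032). These genes were chosen after their values were seen.

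In medullary LCM samples blood endothelial genes were higher and macrophage genes lower. Under 4 of 4 other scalings each list kept its direction and its call at the preset correlation, which argues against scaling as the whole cause. Of these scalings, 1 shifts all genes alike and cannot turn a list. Quantile normalization and the deposited log2 table gave nearly the same LCM counts (15 and 17), so they are not separate tests. Neither list passed with an estimated correlation (camera adjusted p = 0.0622 and 0.138). Blood vessel cells in the dissected medullary material are a candidate source, because a second list of 15 tested blood endothelial genes lay 0.87 above all genes (12 above the median, 0 called) and the dissection stained CD31, which blood vessels also carry. Of the first list, Glycam1 and Plvap differed by 1.78 and 0.39 without being called. Macrophages in the subcapsular material may likewise contribute, as a second list of 14 tested macrophage genes lay at −1.54 (11 below the median, 0 called), and Lyz2 and Itgam of the first list differed by −2.82 and −0.39. In the same comparison 15 housekeeping genes, chosen after seeing the data, lay at −0.9, with 14 below the median. Part of the fall is thus not shown to be specific to macrophage genes. F4/80 staining would have marked macrophages but does not by itself remove them. Of the first lists, 3 of 25 macrophage and 12 of 20 blood endothelial genes stand in other lists, and a difference within the lymphatic endothelium itself stays open.

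Salivary gland genes were high in the FACS samples of both sinuses, where the digested nodes included cervical ones, and whether the podoplanin and CD73 gates would have kept gland cells was not tested. Signal shared by arrays of 1 slide is argued against, because the second salivary list was only 0.17 higher on the medullary LCM arrays of the FACS slide than on those of the other slide. Salivary gland material in the digested nodes stays open: 12 of 14 genes of that list lay above the median of all genes and 5 were called, but the relative median of 1.95 missed the bar of 2 set beforehand. Of its members, Bpifa2 and Amy1 differed by 8.07 and 8.7, while Klk1 differed by −0.2. No other biological explanation was tested, since the isolations differ in node sites, handling and sex-linked transcripts.

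Of 100 splits of the 10 LCM arrays, the real one with 48 called genes was the 1 as large, and 1 of 100 is the lowest share possible. This argues against chance alone only if the samples are independent, which the labels do not say. The highest other split called 37, with subcapsular replicates 1 to 4 and medullary replicate 5 on 1 side. It is the real split with replicate 5 of each sinus exchanged, and is also close to the row of the slide. With the row as a block the sinus comparison called 14, so the splits do not separate the sinus from the row. All 14 arrays were also split 100 times into groups of 4 and 10, drawn within each sinus. The real split, with 1144 genes between FACS and LCM, was the 1 as large, and the highest other called 385. The group of 4 in that other split held subcapsular LCM replicate 1, subcapsular FACS replicate 6 and both medullary FACS arrays, so it is close to the real one. For the correlation of the LCM and FACS sinus differences, 21 of 100 splits were as far from 0 as 0.149, of either sign, with 0.268 the highest other, so chance cannot be excluded.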
